A study of Caulobacter vibrioides NA1000 with 10 samples.

How the data were processed

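RNA of Caulobacter crescentus (named Caulobacter vibrioides in the labels) strain NA1000 was measured on 10 Agilent 2-colour arrays. On every array Cy3 carried total RNA of cells kept in rich medium with vanillate (50 mM per the labels) and Cy5 total RNA of the same strain released into medium without it. The depletion strain lacks *phoU* at its own locus and carries it under the vanillate-inducible promoter Pvan (per the labels). The *pstS* *phoU* strain also carries a Tn5 transposon insertion in *pstS*. The labels form 7 groups. The *phoU* strain has 2 arrays each at 2, 5 and 7 h of depletion and 1 array at 16 h, and the *pstS* *phoU* strain has 1 array each at 2, 7 and 16 h. The arrays sit on 2 slides and were read in 4 scan sessions.

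Per the file headers the scans were read with Agilent Feature Extraction 10.5.1.1, and the spot signals are fluorescence intensity in arbitrary units, given as the median of a spot's pixels with the median of its local background. The same files hold the scanner software's processed intensity, deposited after its own background subtraction and dye normalization. The values that the authors deposited for the series are log10 ratios of Cy5 over Cy3 per spot. On each array these equalled the ratio column of the scanner file within 0.001 (log10) for between 15028 and 15172 of 15199 spots. The mean pixel signal is present in some of the files only, so the median signal was used, as laid down for that case. The models, thresholds, gene lists, rule for named genes and alternatives described here were fixed before the data were examined, except where a later choice is stated.

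Each array has 15735 features, of which 536 are controls. The 15199 other spots carry 15046 probes for 3824 genes and 36 further targets, with a median of 4 probes per gene. Gene coordinates are those of the array annotation for the NA1000 chromosome. Of these genes, 3730 had their locus tag in the reference annotation. *pstS* carries no symbol on the array and was taken as CCNA_01583 from its product name, phosphate-binding protein.

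Signals were background-corrected by normexp with an offset of 50, and log2 ratios were normalised within each array by loess, with controls and outlier spots at weight 0. Spots that the scanner software marked as outliers were left out, spots were averaged per probe, and probes were averaged per gene. Of the genes, 3823 had a value on every array and were tested, and 1 was left out for lacking one. For the comparison of the strains in Cy3 alone, log2 Cy3 signals after the same background correction were quantile-normalised over the 10 arrays. Ratios at each time were tested with limma on a model with 1 mean per strain and time, which gives all groups a shared estimate of spread. A group of 1 array is assumed to vary like the 3 replicated groups of the *phoU* strain, which the noisier 16 h array of that strain did not meet. The spread of the 3 *pstS* *phoU* arrays does not enter the test of their mean. Values within a slide for the strain comparisons are between arrays of the same time, a choice made later. Differences between the strains were tested with limma on an additive model of time and strain. Standard errors are the moderated ones of limma, tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these arrays. Cy5 was the sample without vanillate on every array, so a gene-specific dye effect remains in the ratios. It cancels in the difference between 7 h and 2 h and in the comparisons of the strains.

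The 21 fixed gene lists, with the number of measured members, were Pho signalling and phosphate transport (7), phosphorus scavenging (12), polyphosphate and alarmone (7), vanillate and protocatechuate catabolism (5), ribosomal proteins (55), tRNA synthetases (21), heat shock proteins (12), general stress response (8), oxidative stress (10), SOS and DNA repair (10), cell cycle regulators (19), cell division and wall elongation (17), flagellum and chemotaxis (91), pili and holdfast (27), stalk and stalk regulators (11), TonB-dependent receptors (55), iron uptake and storage (8), ATP synthase and respiratory chain (37), central carbon metabolism (TCA cycle) (5), efflux pumps (29) and transposases and phage (30). Members came from array symbols and product names. An inositol-binding protein that shares the symbol *ibpA* was left out of the heat shock list, a regulator of alkaline phosphatase synthesis out of the scavenging list, and the flagellar ATP synthase out of the respiratory list. After the values were seen, 3 lists were added: inositol catabolism and transport (10), sulfate assimilation (9) and general secretion pathway (12). The added lists were adjusted apart from the fixed ones. List shifts were tested by camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Counts given as over the list alone use p adjusted over the members of that list. Named genes were, for each comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with the same sign on every array of the comparison. For differences, every array of one group had to lie above or below every array of the other. Where no gene passed, up to 5 genes of smallest p were named as not passing. *phoU*, *phoB*, *phoR*, *pstS*, *pstC*, *pstA*, *pstB*, *ppk1*, *vanA*, *vanB* and *vanR* were named in every comparison, with 2 to 4 members of each list, those of smallest p. Genes named outside this rule are marked in the text as chosen later.

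The depth of an array is its signal over background. Median spot signals ranged from 806 to 10952 in Cy3 against local backgrounds from 26.5 to 41.5, at least 99.553% of the spots of each channel were well above background, and no spot was saturated. The number of arrays limits the precision. The 8 comparisons found 192 to 200 of 200 genes with a simulated log2 of 1, with 2 to 17 false calls. This need not hold for the noisier 16 h array or the strain difference in ratios.

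Alternatives were the scanner software's processed signals, the deposited ratios, no background subtraction, median centring in place of loess, scale or average-intensity quantile normalization between arrays, a filter on dim probes (well above background on at least 5 arrays), the median of the probes, an intensity trend in the variance model, and a minimum log2 change of 1. Others were blocks for replicate number, slide and scan session, fits on subsets of the arrays, a model with 1 mean per strain and time for the strain comparisons, median or 75th percentile scaling of Cy3, an estimated correlation for the lists, and leaving out each array in turn. A fit without the 16 h arrays of both strains was added after the data were seen, and so was an error for the 16 h array raised by its probe noise variance beyond the mean of the 6 replicated arrays. An error for the *pstS* *phoU* mean from the spread of its own 3 arrays was also added. The 36 targets without a gene name on the array were tested apart from the genes. Control features were not used in any comparison. R 4.3.3, limma 3.58.1 and jsonlite 2.0.0 were used for the analysis, and Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 for the plots.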

Results

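Transcript levels in cells deprived of PhoU, a phosphate signalling protein, were compared with those in cells of the same strain that still expressed it. No strain kept *phoU* on without vanillate, so a ratio alone cannot tell PhoU loss from vanillate loss. The *phoU* strain was depleted for 2, 5 and 7 h (2 arrays each) and 16 h (1 array). The strain with an insertion in *pstS*, for the periplasmic phosphate-binding protein, was sampled at 2, 7 and 16 h (1 array each). The median spot signal in Cy3 was highest on the *phoU* 2 h replicate 1 array (10951.5) and in Cy5 on the *phoU* 5 h replicate 1 array (9720.5). Both were lowest on the *pstS* *phoU* 7 h array (806 in Cy3 and 665.5 in Cy5), against local backgrounds of 37 and 60. Across genes, the log2 ratio of the sample without vanillate over the sample with it had an SD between 0.296 and 0.362 on 9 of the arrays and of 0.937 on the *phoU* 16 h array. The *phoU* transcript itself was lower without vanillate on each of the 10 arrays, with log2 ratios between -4.30 and -2.82 in the *phoU* strain and between -5.33 and -4.61 in the *pstS* *phoU* strain. The log2 Cy3 signal of *pstS* lay between 13.88 and 14.41 on the arrays of the *phoU* strain and between 11.86 and 11.95 on those of the *pstS* *phoU* strain. Values are log2 ratios with the standard error (SE) of the fit, and n is the number of arrays. Where a group has 1 array there is no replicate, and its error was taken from the replicated groups.

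The first comparison asked which transcripts had changed 2 h after vanillate was withdrawn in the *phoU* strain (n = 2). *phoU* (chromosome 1, 309660 to 310349) fell by 4.06 ± 0.21 (SE, adjusted p = 0.000185), with log2 ratios of -3.83 and -4.30 on its arrays. The genes of vanillate breakdown fell as well: *vanA* (chromosome 1, 2620910 to 2621983), which encodes a subunit of vanillate demethylase, fell by 4.48 ± 0.22 (SE, adjusted p = 0.000185), *vanB* had a log2 ratio of -4.50 ± 0.24 (SE, adjusted p = 0.000185) and the regulator gene *vanR* one of -1.96 ± 0.17 (SE, adjusted p = 0.00214). The other large falls were in genes for the breakdown of protocatechuate, the product of vanillate demethylation, and related acids: CCNA_02488 (-5.12) and CCNA_02489 (-4.69), annotated as subunits of a 3-ketoacid CoA transferase, CCNA_02487 (-4.79), annotated as 4-hydroxybenzoate 3-monooxygenase, the thiolase genes CCNA_01168 (-3.93) and CCNA_02490 (-3.80), CCNA_02494 (-3.75) and the protocatechuate dioxygenase gene CCNA_02491 (-4.53). Of the 5 members of the vanillate and protocatechuate list, 5 fell and none rose (0 up and 5 down over the list alone). The list median was -4.48 (adjusted p = 2.9e-10, and 0.593 with an estimated correlation). The phosphate genes showed no call besides *phoU*: the log2 ratios were *pstS* (-0.20), *pstC* (-0.081), *pstA* (-0.011), *pstB* (-0.073), *phoB* (-0.12), *phoR* (0.034) and *ppk1* (-0.043), none passing. The Pho signalling list, which includes *phoU*, had a median of -0.081, or -0.13 with median centring (adjusted p = 0.0367, and 0.593 with an estimated correlation), and did not pass with a slide block (adjusted p = 0.0572).

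The rises at 2 h were smaller. The translation elongation factor gene CCNA_01298 rose by 0.50 ± 0.063 (SE, adjusted p = 0.0159) and *rpsC*, for ribosomal protein S3, by 0.39 ± 0.056 (SE, adjusted p = 0.0295), and the other 4 were CCNA_00438 (0.80), CCNA_01186 (0.63), CCNA_00744 (0.51) and CCNA_01405 (0.48), all annotated as hypothetical. *znuL*, for a TonB-dependent receptor, fell by 0.99 ± 0.11 (SE, adjusted p = 0.00833). None passed in the lists of general stress response (8 genes), SOS and DNA repair (10), flagellum and chemotaxis (91) or transposases and phage (30). Over the list alone the SOS list had 0 up and 5 down, and the others 0 up and 0 down. By camera the medians were, in that order, -0.13 (adjusted p = 0.0367) and -0.15, 0.055 and 0.12 (adjusted p = 0.00728 each). With an estimated correlation adjusted p was 0.593 for each. The respiratory list had a median of -0.068, or 0.16 with median centring (adjusted p = 0.0498, and 0.593 with an estimated correlation), and did not pass with a slide block either (adjusted p = 0.0594). Of the lists chosen later, the inositol list had a median of 0.44, where none passed (4 up and 0 down over the list alone, and for the list shift adjusted p = 1.97e-05, and 0.322 with an estimated correlation), and the sulfate list one of -0.43, where 5 fell and none rose (0 up and 7 down over the list alone, and for the list shift adjusted p = 1.83e-07, and 0.139 with an estimated correlation). Over all genes, limma called 39 of 3823, 6 up and 33 down, each with the same sign on both arrays, and 20 of them changed by at least 1, all downwards. Without *phoU* 2 h replicate 1 the count was 22, and 7 of the 18 named genes that passed no longer did, among them CCNA_01298 (0.52, adjusted p = 0.187), *rpsC* (0.41, adjusted p = 0.272) and *znuL* (-1.08, adjusted p = 0.0776). Without *phoU* 2 h replicate 2, 7 of the 18 named genes that passed no longer did, and without a 5 h or a 7 h array of the *phoU* strain 4 and 2 of them did not. The genes lost without a 5 h or a 7 h array were all among the 6 rises, none of which passed with an intensity trend. With the scanner software's processed signals or the deposited ratios 5 of the 6 did not pass.

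The question at 5 h was the same (n = 2). *phoU* was lower by the same test (-3.58 ± 0.21 SE, adjusted p = 0.000316), as were *vanA* (-4.36), *vanB* (-4.49) and the CoA transferase and dioxygenase genes CCNA_02488 (-5.01), CCNA_02489 (-4.78) and CCNA_02491 (-4.50). CCNA_02487, CCNA_01168, CCNA_02490, CCNA_02493 and CCNA_02494 fell as well, with log2 ratios between -5.06 and -3.84. Genes for the breakdown and uptake of inositol rose: *idhA* (chromosome 1, 1468215 to 1469198), which encodes myo-inositol 2-dehydrogenase, by 1.5 ± 0.15 (SE, adjusted p = 0.00377), the catabolic genes *iolB* (1.31), *iolE* (1.08), *iolC* (1.06), *iolD* (1.05) and *iolA* (0.92), and the transporter genes *ibpA* (1.14) and *iatP* (0.96). Of the 10 members of the inositol list, which was chosen after the values were seen, 8 rose and none fell (9 up and 0 down over the list alone). The list had a median of 1.05 (adjusted p = 1.99e-11, and 0.134 with an estimated correlation). The sulfate assimilation list, also chosen later, moved the other way. Of its 9 members, 6 fell and none rose (0 up and 8 down over the list alone). Here the list median was -0.59 (adjusted p = 2.63e-10, and 0.0913 with an estimated correlation). Of the 5 members of the vanillate and protocatechuate list, 5 fell and none rose (0 up and 5 down over the list alone). The median over the list was -4.36 (adjusted p = 1.17e-09, and 0.416 with an estimated correlation). Ribosomal protein genes had small rises, among them *rplN* (0.44), *rpsC* (0.38) and *rpsK* (0.51). Of 55 members, 4 rose and none fell (12 up and 0 down over the list alone). These genes had a median of 0.13 (adjusted p = 7.02e-05, and 0.576 with an estimated correlation). With median centring the median of this list was 0.80, and with the scanner software's processed signals 0.087. In the SOS and DNA repair list, 1 fell and none rose (0 up and 7 down over the list alone). The list median was -0.18 (adjusted p = 7.02e-05, and 0.416 with an estimated correlation). The member that passed was *sidA* (-0.65), a division inhibitor gene. *pstS*, *pstC*, *pstA*, *pstB*, *phoB* and *phoR* had log2 ratios between -0.08 and 0.075, and none passed.

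Other lists shifted at 5 h too: general stress (median -0.17), efflux (-0.083), TonB-dependent receptors (0.053, where 3 rose and 1 fell), tRNA synthetases (-0.076, or 0.021 with median centring) and respiratory genes (-0.091, or 0.15 with median centring). Their adjusted p lay between 0.0029 and 0.0401, and between 0.416 and 0.576 with an estimated correlation. In all, 89 genes passed at 5 h, 37 up and 52 down, each with the same sign on both arrays, and 30 changed by at least 1. Falls shared with 2 h numbered 31 against 0.449 expected for independent lists, and rises 6 against 0.0581. Such lists are not independent here or below, since the fits share each gene's spread estimate and the dye orientation. An excess alone does not show a shared response. With median centring in place of loess, 48 rose and 35 fell. Without *phoU* 5 h replicate 2 the count was 24 and 21 of the 33 named genes that passed no longer did, among them *idhA* (1.27, adjusted p = 0.0727), *iolA* (0.57, adjusted p = 0.209), *iolC* (0.62, adjusted p = 0.332), *iolD* (0.64, adjusted p = 0.332), *iolE* (0.67, adjusted p = 0.186), *ibpA* (0.85, adjusted p = 0.0867), *iatP* (0.83, adjusted p = 0.124), *rplN* (0.55, adjusted p = 0.062) and *sidA* (-0.49, adjusted p = 0.332). It was 46 without *phoU* 5 h replicate 1, with *rplN*, *rpsC*, *rpsK* and *sidA* among the 10 named genes lost, and 55 without either 2 h array of the *phoU* strain, each left out singly, with *iolA*, *iolC*, *iolD* and *iolE* among the 12 lost. With an intensity trend none of the inositol genes named here was called at 5 h (*idhA*, adjusted p = 0.321), and with median centring *iolA*, *iolC*, *iolD* and *iolE* were not. The scanner software's processed signals and the deposited ratios each lost 10 of the 33 named calls, among them *iolA*, *iolC*, *iolD*, *rplN*, *rpsC* and *sidA* (adjusted p between 0.052 and 0.109 with the processed signals).

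At 7 h, the latest time with replicates (n = 2), the genes of phosphate uptake and its regulator had risen in the *phoU* strain. *pstB* (chromosome 1, 308759 to 309631), for the ATPase of the phosphate transporter, rose by 1.33 ± 0.054 (SE, adjusted p = 0.000104), with an SD of 0.062 between the arrays, and the permease genes *pstC* (chromosome 1, 306029 to 307459) by 1.32 ± 0.06 (SE, adjusted p = 0.000126) and *pstA* (chromosome 1, 307455 to 308747) by 1.09 ± 0.071 (SE, adjusted p = 0.000503). *phoB* (chromosome 1, 310374 to 311063), for the response regulator of the phosphate starvation response, rose by 1.02 ± 0.073 (SE, adjusted p = 0.000789). These 4 genes lie beside the *phoU* locus, while *pstS* (chromosome 1, 1698524 to 1699561) lies elsewhere and had a log2 ratio of 0.14 ± 0.056 (SE, adjusted p = 0.153). *phoR*, for the sensor kinase, stood at -0.05 ± 0.051 (SE, adjusted p = 0.543) and *ppk1*, for polyphosphate kinase, at -0.076 ± 0.052 (SE, adjusted p = 0.374). *phoU* was still lower, at -3.26 ± 0.21 (SE, adjusted p = 0.000487). Of the 7 genes of the Pho signalling list, 4 rose and 1 fell (5 up and 1 down over the list alone). The median of the list was 1.02 (adjusted p = 0.00106, and 0.304 with an estimated correlation). In the phosphorus scavenging list of 12 genes, 1 rose and none fell (4 up and 2 down over the list alone), the called one being the phospholipase C gene CCNA_03126 (0.32), and the list did not shift (adjusted p = 0.492, and 0.628 with an estimated correlation).

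Inositol genes were higher at 7 h too, with *idhA* at 1.75 ± 0.15 (SE, adjusted p = 0.00143), *iolB* at 1.56, *ibpA* at 1.49, *iolE* at 1.41, *iolD* at 1.38, *iolA* at 1.20, *iolC* at 1.16 and *iatP* at 1.15. Of the 10 members of this list, chosen later, 8 rose and none fell (10 up and 0 down over the list alone). For this list the median was 1.29 (adjusted p = 3.57e-11, and 0.138 with an estimated correlation). The falls were again led by CCNA_02488 (-4.65), CCNA_02487 (-4.27), CCNA_02489 (-4.26), CCNA_02491 (-4.17), *vanA* (-4.04 ± 0.22 SE, adjusted p = 0.000286) and *vanB* (-3.96), with CCNA_01168, CCNA_02490, CCNA_02494 and CCNA_02493 between -3.78 and -3.41 and *vanR* at -1.56. In the vanillate and protocatechuate list 5 fell and none rose (0 up and 5 down over the list alone). Its members had a median of -3.96 (adjusted p = 2.66e-07, and 0.304 with an estimated correlation). Sulfate assimilation genes fell, among them *cysH* (-0.81), *cysI* (-0.77) and CCNA_01550 (-0.68). Of the 9 members of this list, chosen later, 6 fell and none rose (0 up and 7 down over the list alone). The median value of the list was -0.48 (adjusted p = 1.75e-05, and 0.138 with an estimated correlation). Of 55 ribosomal protein genes, 7 rose and none fell (19 up and 2 down over the list alone). The list had a median of 0.16 (adjusted p = 1.07e-05, and 0.526 with an estimated correlation), with *rplN* (0.56), *rpsK* (0.50) and *rpsC* (0.45) the members of smallest p. With median centring the median of this list was 0.66, and with the scanner software's processed signals 0.099. Among 55 TonB-dependent receptors, which take up bound nutrients through the outer membrane, 9 rose and 3 fell (15 up and 7 down over the list alone). Here the list median was 0.13 (adjusted p = 0.00106, and 0.327 with an estimated correlation), with rises of CCNA_01047 (0.89), CCNA_00615 (0.82) and CCNA_00338 (0.75) and a fall of *znuL* (-0.82). In the iron list, where 2 rose and none fell (2 up and 0 down over the list alone), with a list median of 0.16 (adjusted p = 0.0178, and 0.304 with an estimated correlation), the risers were *exbB* (0.73) and *tonB1* (0.47), parts of the complex that powers such receptors. Median centring moved the median of the receptor list to 0.36 and that of the iron list to 0.43.

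Smaller shifts were seen in other lists at 7 h. In the SOS list of 10 genes, 2 fell and none rose (0 up and 3 down over the list alone). The median over the list was -0.13 (adjusted p = 0.00809, and 0.327 with an estimated correlation), with *sidA* (-0.65) and *recA* (-0.30). The 37 genes of ATP synthase and the respiratory chain, among them CCNA_03558 (-0.37), *nuoG* (-0.28) and *coxB* (-0.28), had a median of -0.17, which was 0.017 with median centring, and 3 fell and none rose (2 up and 21 down over the list alone, and for the list shift adjusted p = 5.67e-05, and 0.327 with an estimated correlation). *coxB*, for a cytochrome c oxidase subunit, stood at 0.091 with median centring. Of the 11 stalk genes, 1 fell and none rose (0 up and 2 down over the list alone). These genes had a median of -0.11 (adjusted p = 0.0199, and 0.304 with an estimated correlation), with *stpB* at -0.24. Of 29 efflux genes 1 fell and none rose (0 up and 1 down over the list alone). The list median was -0.075 (adjusted p = 0.00362, and 0.304 with an estimated correlation), with CCNA_03300 at -0.32. The 91 flagellum and chemotaxis genes had a median of 0.035, where 2 rose and none fell (0 up and 0 down over the list alone, and for the list shift adjusted p = 0.0316, and 0.628 with an estimated correlation). In the 30 genes of transposases and phage none passed (0 up and 0 down over the list alone). Nor did any in general secretion, chosen later (5 up and 0 down). The medians were 0.16 and 0.17 (adjusted p = 0.00125 and 0.000199, and 0.526 and 0.149 with an estimated correlation). Median centring moved the medians to -0.21 for the SOS list, -0.19 for the stalk list, 0.31 for the transposase list and 0.31 for the general secretion list. The other fixed lists did not shift at 7 h. The cell cycle list had 1 call, *gcrA* (-0.48), for a cell cycle regulator, and the oxidative stress list 1, *ahpF* (-0.29). None passed in the lists of polyphosphate and alarmone (7 genes), tRNA synthetases (21), heat shock (12), general stress response (8), cell division (17), pili and holdfast (27) or central carbon metabolism (5), with adjusted p between 0.111 and 0.882 for the shifts of these 9 lists.

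In total 187 genes passed at 7 h, 86 up and 101 down, each with the same sign on both arrays. 32 of them changed by at least 1, 12 up and 20 down. Rises shared with 5 h numbered 29 against 0.832 expected for independent lists, and falls 41 against 1.37. *pstC*, *pstA*, *pstB* and *phoB* passed under each processing alternative and without each array in turn, but the count did not hold. It was 67 with median centring (36 up and 31 down) and 76 with scale normalization, 46 without *phoU* 7 h replicate 1 (16 up and 30 down), 99 without *phoU* 7 h replicate 2 (64 up and 35 down), 71 without either 5 h array and 111 without either 2 h array of the *phoU* strain, each left out singly. Without *phoU* 7 h replicate 1, 25 of the 46 named genes that passed no longer did, among them *iolA* (1.09, adjusted p = 0.0976), *iolC* (1.14, adjusted p = 0.138), *iolD* (1.18, adjusted p = 0.107), *iolE* (1.30, adjusted p = 0.09), *vanR* (-1.33, adjusted p = 0.0506), CCNA_01047 (0.69, adjusted p = 0.0506), *exbB* (0.55, adjusted p = 0.0891) and *rplN* (0.56, adjusted p = 0.0688). With replicate 2 left out, 17 did not, among them *iolC*, *rpsC*, *sidA* and *tonB1*, and without a 5 h or a 2 h array of this strain 12 and 8 did not, among them CCNA_03300, *ahpF*, *coxB*, *gcrA*, *nuoG* and *stpB* in both cases. With an intensity trend *idhA*, *ibpA*, *iolB*, *iolC* and *iolD* were not called, *idhA* having an adjusted p of 0.189, and 45 genes rose and 110 fell. The scavenging gene CCNA_03126 was not called with median centring (adjusted p = 0.125), with scale normalization (0.0509), or without any 1 of the 5 h and 7 h arrays (0.0724 to 0.152). Of the 46 named calls median centring lost 13, scale normalization 16, and the processed signals and the deposited ratios 9 each, in every case with *ahpF*, *coxB*, *gcrA*, *nuoG*, *stpB* and *tonB1* among them.

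**Figure D1:**
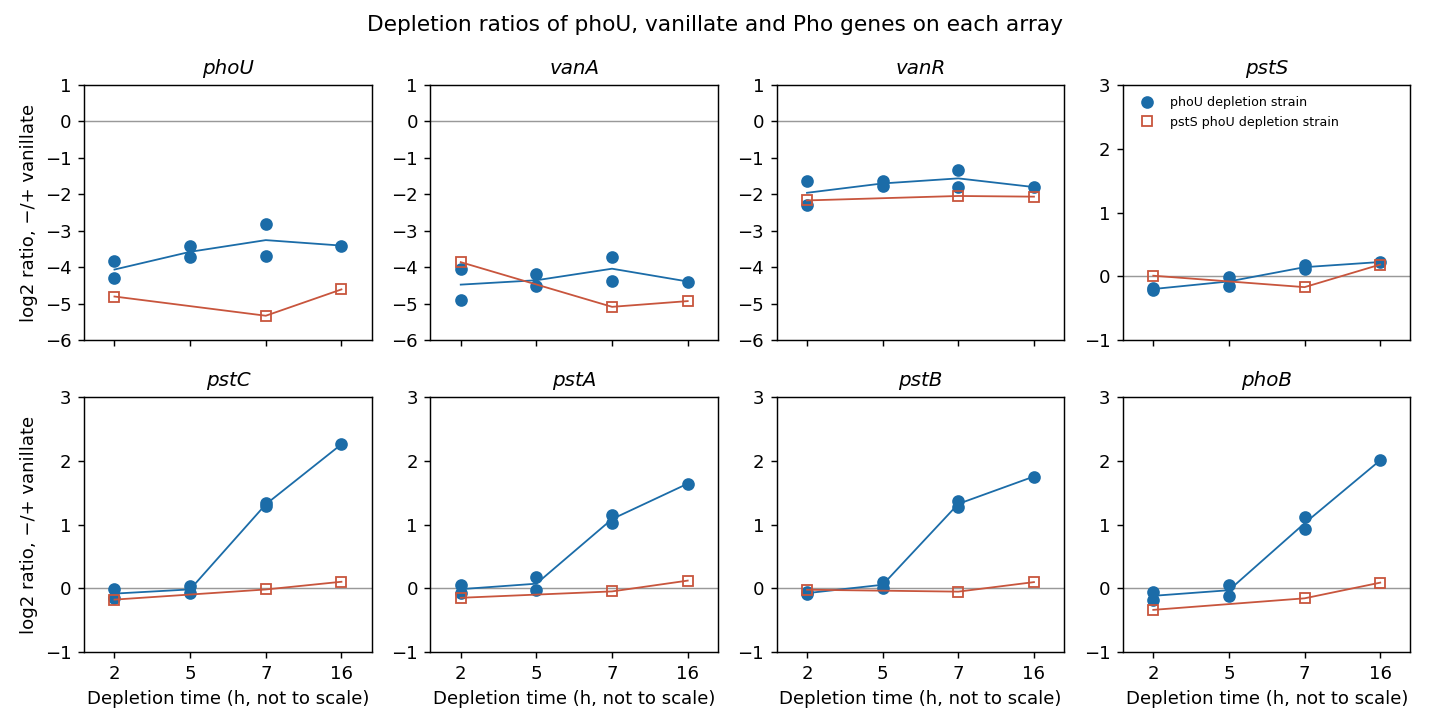
Log2 ratio of the sample without vanillate over the sample with it for phosphate and vanillate genes (vertical axis), 1 point per array, against hours of depletion (horizontal axis, not to scale) in the *phoU* strain (filled symbols) and the *pstS* *phoU* strain (open symbols). On the 7 h arrays of the *phoU* strain *pstC* lies at 1.34 and 1.30, while on the *pstS* *phoU* 7 h array it lies at -0.016.

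The change between 2 h and 7 h in the *phoU* strain was tested on its own (2 arrays against 2), since a dye effect of a gene cancels in it. Phosphate genes beside *phoU* made up most of the calls: *pstC* rose by 1.40 ± 0.084 (SE, adjusted p = 0.00208), *pstB* by 1.40 ± 0.076 (SE, adjusted p = 0.00208), *phoB* by 1.14 ± 0.10 (SE, adjusted p = 0.0155) and *pstA* by 1.1 ± 0.10 (SE, adjusted p = 0.0155). The remaining 2 were CCNA_00206, which rose by 0.84 ± 0.085 (SE, adjusted p = 0.0235), and CCNA_00207, by 0.71 ± 0.079 (SE, adjusted p = 0.0339), annotated as subunits of a succinyl-CoA:3-ketoacid CoA transferase. Within slide 1 the differences were 1.49 for *pstC*, 1.46 for *pstB*, 1.29 for *phoB* and 1.1 for *pstA*, and within slide 2 they were 1.31, 1.34, 0.98 and 1.1. *phoU* (0.81 ± 0.29 SE, adjusted p = 0.995) and *pstS* (0.34 ± 0.079 SE, adjusted p = 0.734) did not pass. In the Pho signalling list 4 rose and none fell (6 up and 0 down over the list alone). Its members had a median of 1.1 (adjusted p = 7.48e-17, and 0.0971 with an estimated correlation). The ribosomal list had a median of 0.09 where none passed (0 up and 0 down over the list alone, and for the list shift adjusted p = 8.21e-07, and 0.486 with an estimated correlation). In the inositol list, chosen later, none passed (8 up and 0 down over the list alone). The median value of the list was 0.86 (adjusted p = 1.51e-15, and 0.183 with an estimated correlation). Further shifts, with no member passing, were upward in the lists of vanillate (0.40), iron (0.19), TonB-dependent receptors (0.061) and general secretion, chosen later (0.13) and downward in those of cell cycle (-0.093), stalk (-0.10) and respiratory genes (-0.069). Their adjusted p lay between 0.000169 and 0.0205, and between 0.208 and 0.502 with an estimated correlation. Scale normalization moved the vanillate median to 1.21, and median centring those of the ribosomal list to 0.045, the receptors to 0.18, the respiratory genes to -0.14 and general secretion to 0.24. Over all genes 6 passed, 6 up and 0 down, and 149 had an unadjusted p below 0.05. With median centring none passed: the differences of *pstC* and *pstB* were then 1.37 and 1.37 with adjusted p = 0.104 and 0.106, with 54 genes at an unadjusted p below 0.05. A block for the replicate number or the slide left 3 calls, *pstC*, *pstB* and *pstA*, and scale normalization 2. Without either 2 h array or without *phoU* 7 h replicate 1 there were 2 calls, *pstC* and *pstB*, and *phoB* then had adjusted p = 0.143, 0.13 and 0.0937, and *pstA* 0.124, 0.183 and 0.0937. Without *phoU* 7 h replicate 2 there were 14 calls, and without it or a 5 h array CCNA_00206 and CCNA_00207 were not among them.

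After 16 h the *phoU* strain was measured on 1 array, whose spread of ratios was the widest of the 10, and its values have no replicate. The noise SD of a gene mean, from odd and even probes, was 0.212 on it against 0.0626 to 0.114 on the others. The SE at this time (median 0.0888), taken from the replicated groups, is therefore too small, and so are its p-values. Counts with the SE raised by the extra noise of the array, chosen later, are given beside them as the raised error. The largest rises were in *cspD*, for a cold shock protein, by 5.25 ± 0.094 (SE, adjusted p = 5.17e-07), the TonB-dependent receptor genes CCNA_01047, by 5.03 ± 0.15 (SE, adjusted p = 1.13e-06), and CCNA_00759, by 4.92 ± 0.068 (SE, adjusted p = 2.24e-07), the response regulator gene CCNA_02783 (4.06), the monooxygenase gene CCNA_02034 (3.99) and CCNA_03795, annotated as the tellurium resistance gene terB (3.84). CCNA_00169, CCNA_03762, CCNA_03327 and CCNA_00884, all hypothetical, rose by between 3.83 and 4.87. The phosphate genes stood at *pstC* (2.26), *phoB* (2.01), *pstB* (1.75) and *pstA* (1.64), with *phoR* lower at -1.0, *pstS* at 0.22 ± 0.079 (SE, adjusted p = 0.0371) and *ppk1* at -0.10 ± 0.074 (SE, adjusted p = 0.239). In the Pho signalling list 5 rose and 2 fell (5 up and 2 down over the list alone) and the list did not shift as a whole (adjusted p = 0.258, and 0.581 with an estimated correlation). *phoU* fell by 3.41 ± 0.29 (SE, adjusted p = 6.25e-05), with *vanA* at -4.39 ± 0.31 (SE, adjusted p = 3e-05) and *vanB* at -4.55 ± 0.33 (SE, adjusted p = 3.32e-05). CCNA_02487, CCNA_02488, CCNA_02489, CCNA_02491, CCNA_02493 and CCNA_02494 lay between -5.23 and -4.14, and the genes of formaldehyde breakdown at CCNA_02600 (-3.90) and CCNA_02601 (-3.50). In the vanillate and protocatechuate list 5 fell and none rose (0 up and 5 down over the list alone). The list had a median of -4.39 (adjusted p = 0.0141, and 0.581 with an estimated correlation). With the raised error the numbers that rose and fell were 4 and 2 in the Pho signalling list and 0 and 5 in the vanillate list.

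The median ratios of flagellum, stalk, pilus and cell cycle genes were below 0 on the 16 h array. Of 91 flagellum and chemotaxis genes, 20 rose and 50 fell (20 up and 51 down over the list alone). Here the list median was -0.32 (adjusted p = 0.00885, and 0.581 with an estimated correlation), with *flgE*, for the hook protein, at -2.04 and *flgA* at -1.33. Among 11 stalk genes 1 rose and 10 fell (1 up and 10 down over the list alone). The median over the list was -0.84 (adjusted p = 0.00885, and 0.581 with an estimated correlation), with *tacA* (-1.44), *stpB* (-1.27) and *bacA* (-1.19). Among 27 genes of pili and holdfast 2 rose and 17 fell (3 up and 18 down over the list alone). These genes had a median of -0.42 (adjusted p = 0.00935, and 0.581 with an estimated correlation), with *hfsJ* (-1.57) and *hfaD* (-1.19). Of 19 cell cycle regulators, 3 rose and 13 fell (3 up and 13 down over the list alone). The list median was -0.47 (adjusted p = 0.0253, and 0.581 with an estimated correlation), including *sciP* (-2.35), *pleD* (-1.26) and *podJ* (-1.1). Of 17 division genes 4 rose and 8 fell (4 up and 8 down over the list alone), with *ftsL* (2.24), *ftsI* (1.73), *ftsZ* (1.36) and *mipZ* (-1.40), with no list shift (adjusted p = 0.498, and 0.699 with an estimated correlation). The SOS and DNA repair list had a median above 0: of 10 genes 8 rose and none fell (8 up and 0 down over the list alone). The median of the list was 0.67 (adjusted p = 0.0136, and 0.581 with an estimated correlation), with the mutagenic repair genes *imuA* (2.38), *imuB* (1.90) and *dnaE2* (1.28). Of 30 transposase and phage genes 20 rose and 3 fell (21 up and 3 down over the list alone). For this list the median was 0.54 (adjusted p = 0.00885, and 0.581 with an estimated correlation), with CCNA_00978 (3.74) and CCNA_02506 (2.92). In the respiratory list 10 rose and 23 fell (10 up and 23 down over the list alone). Its members had a median of -0.38 (adjusted p = 0.0387, and 0.581 with an estimated correlation), with *nuoF* at -1.59. Of 8 general stress genes 6 rose and none fell (6 up and 0 down over the list alone). The median value of the list was 0.72 (adjusted p = 0.0551, and 0.581 with an estimated correlation), with *sigU* (1.60) and *phyK* (1.19), so that the shift did not pass. In the heat shock list 6 rose and 4 fell (6 up and 4 down over the list alone), including CCNA_02341 (2.64), *rpoH* (2.35) and *clpB* (1.21), again with no list shift (adjusted p = 0.47, and 0.699 with an estimated correlation). Among scavenging genes 5 rose and 3 fell (5 up and 3 down over the list alone), among them the phosphodiesterase gene CCNA_03381 (2.29) and the phytase gene CCNA_01353 (1.05), and the list did not shift (adjusted p = 0.607, and 0.699 with an estimated correlation). In the general secretion list, chosen later, 12 rose and none fell (12 up and 0 down over the list alone). The list had a median of 2.29 (adjusted p = 1.11e-06, and 0.233 with an estimated correlation), with *pulF* (3.03), *pulD* (2.78) and *pulE* (2.70). In the sulfate list, also chosen later, 6 fell and none rose (0 up and 6 down over the list alone). Here the list median was -0.60 (adjusted p = 0.0382, and 0.403 with an estimated correlation). With the raised error the numbers that rose and fell were 7 and 35 in the flagellum list, 0 and 6 in the stalk list, 0 and 6 in the pili and holdfast list, 2 and 6 in the cell cycle list, 3 and 2 in the division list, 5 and 0 in the SOS list and 8 and 1 in the transposase list. They were 3 and 12 in the respiratory list, 5 and 0 in the general stress list, 5 and 2 in the heat shock list, 3 and 2 in the scavenging list, 12 and 0 in the general secretion list and 0 and 4 in the sulfate list. By camera on the values with the raised error the same lists shifted, with adjusted p between 2.45e-08 and 0.037 at the preset correlation.

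At this time 2831 of 3823 genes passed, 1433 up and 1398 down, and 816 changed by at least 1, 525 up and 291 down. With the raised error (median SE 0.211) 1494 passed, 838 up and 656 down, with 523 rises and 290 falls of at least 1, and 12 of the 103 named genes that passed no longer did, among them *pstS* (0.22, adjusted p = 0.42). Rises shared with 7 h numbered 54 against 32.2 expected for independent lists, and falls 62 against 36.9. With the raised error they numbered 35 against 18.9 and 39 against 17.3. The scanner software's processed signals gave 1343 rises and 1612 falls, and no background subtraction 1434 and 1450. With scale normalization, which gives every array the same spread and so shrinks this one, 173 genes passed, 160 up and 13 down. The list medians shrank with it, that of the flagellum list to -0.093 and that of general secretion to 0.66. The value of *phoU* was then -0.99 (adjusted p = 0.46), that of *phoB* 0.58 (adjusted p = 0.0525), and 76 of the 103 named genes that passed no longer did. *pstS* did not pass without either 2 h array (adjusted p = 0.0549), with median centring, with a slide block or with the scanner software's processed signals.

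In the strain with the *pstS* insertion the depletion ratios were averaged over 2, 7 and 16 h (n = 3), to ask which responses to the withdrawal of vanillate occur when *pstS* is disrupted. Each time has 1 array, so the SE comes wholly from the replicates of the *phoU* strain, and the spread of these 3 arrays does not enter the test. *phoU* fell by 4.92 ± 0.17 (SE, adjusted p = 3.37e-05), with *vanA* at -4.63 ± 0.18 (SE, adjusted p = 4.9e-05) and *vanB* at -3.94 ± 0.19 (SE, adjusted p = 0.000132). Further falls were CCNA_02488 (-4.80), CCNA_02489 (-4.57), CCNA_02491 (-4.53), CCNA_02487 (-4.23), CCNA_02494 (-3.60), CCNA_02493 (-3.26), CCNA_02601 (-3.07) and *vanR* (-2.09). In the vanillate and protocatechuate list 5 fell and none rose (0 up and 5 down over the list alone). The median over the list was -3.94 (adjusted p = 4.11e-07, and 0.559 with an estimated correlation). None of the other phosphate genes passed, with log2 ratios of *pstC* (-0.029), *pstA* (-0.023), *pstB* (0.0098), *phoB* (-0.13), *phoR* (0.07), *pstS* (0.0078) and *ppk1* (-0.045). In the Pho signalling list 1 fell and none rose (0 up and 1 down over the list alone, and for the list shift adjusted p = 0.39, and 0.667 with an estimated correlation). Most of its members were already higher in Cy3 of this strain, as given below. The largest rises were in the TonB-dependent receptor genes CCNA_01021, by 1.40 ± 0.17 (SE, adjusted p = 0.00504), with an SD of 0.85 between the arrays, and CCNA_01042, by 1.09 ± 0.11 (SE, adjusted p = 0.00232), the bacterioferritin gene CCNA_03371 (0.81), the amino acid breakdown genes CCNA_00619 (0.98) and CCNA_00620 (0.97), the hydrolase gene CCNA_01406 (0.81), the fatty acid breakdown genes CCNA_03575 (0.77) and CCNA_01368 (0.73), *idhA* (0.79) and the hypothetical CCNA_00425 (0.69). With an error taken from the 3 arrays themselves none of these 10 rises passed (adjusted p between 0.0541 and 0.121). Of 55 TonB-dependent receptors, 22 rose and 2 fell (29 up and 3 down over the list alone). These genes had a median of 0.17 (adjusted p = 1.47e-06, and 0.559 with an estimated correlation). Of 91 flagellum and chemotaxis genes, 16 rose and 1 fell (18 up and 1 down over the list alone). The list median was 0.083 (adjusted p = 0.000317, and 0.613 with an estimated correlation), with *cheY* (0.36), *fliN* (0.34) and *flgF* (0.38). In the iron list 2 rose and 3 fell (2 up and 4 down over the list alone), with falls of the bacterioferritin-associated ferredoxin gene CCNA_03372 (-1.25) and of the ferrous iron transport gene CCNA_00748 (-0.71), without a list shift (adjusted p = 0.241, and 0.613 with an estimated correlation). Of the lists chosen later, the inositol list had a median of 0.48, where 6 rose and none fell (9 up and 0 down over the list alone, and for the list shift adjusted p = 0.00012, and 0.236 with an estimated correlation), the sulfate list one of -0.14, where 3 fell and none rose (0 up and 4 down over the list alone, and for the list shift adjusted p = 0.00154, and 0.226 with an estimated correlation), and the general secretion list one of -0.18, where 5 fell and none rose (0 up and 6 down over the list alone, and for the list shift adjusted p = 0.000191, and 0.226 with an estimated correlation). In the general stress list 2 fell and none rose (0 up and 4 down over the list alone), with *sigT* at -0.33. In the SOS list 3 fell and none rose (0 up and 3 down), with *imuA* at -0.41. Their medians were -0.16 and -0.087 (adjusted p = 0.0367 and 0.0414, and 0.613 for both with an estimated correlation). The SOS shift did not pass with a slide block (adjusted p = 0.0676). With the error from the 3 arrays themselves the numbers that rose and fell were 0 and 5 in the vanillate list, 1 and 1 in the receptor list, 0 and 0 in the flagellum list and 0 and 3 in the iron list, and none passed in the stress, SOS, inositol, sulfate or general secretion lists. The list shifts passed with that error too (adjusted p between 2.76e-11 and 0.0161), except that of the SOS list (adjusted p = 0.0528).

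Altogether 724 genes passed for this strain, 376 up and 348 down, of which 662 had the same sign on each of the 3 arrays and 23 changed by at least 1, 2 up and 21 down. With the error from the 3 arrays themselves, times pooled, an alternative chosen later, 31 passed, 4 up and 27 down, and 50 of the 66 named genes that passed no longer did. *phoU*, *vanA* and *vanB* still passed. Rises shared with the *phoU* strain at 7 h numbered 34 against 8.46 expected for independent lists, and falls 57 against 9.19. These lists are not independent, and both hold the vanillate genes. With the *phoU* strain at 16 h the shared rises were fewer than expected (50 against 82.4 with the raised error) and the falls 73 against 59.7, or 87 against 141 and 143 against 127 without it. Median centring left 72 genes, and 44 of the 66 named genes that passed no longer did. A replicate block left 254, and with the scanner software's processed signals 566 rose and 337 fell. An intensity trend gave 383 rises and 404 falls, and the fit without either *phoU* 2 h array 292 and 295. Without the *pstS* *phoU* 2 h array 109 passed (54 up and 55 down) and 46 of the 66 named genes that passed no longer did, among them CCNA_01042 (0.67, adjusted p = 0.0529), CCNA_00619 (1.1, adjusted p = 0.12), CCNA_03371 (0.60, adjusted p = 0.0848), *idhA* (0.49, adjusted p = 0.166), *fliN* (0.27, adjusted p = 0.0617), *flgF* (0.22, adjusted p = 0.147), *sigT* (-0.21, adjusted p = 0.229) and *imuA* (-0.31, adjusted p = 0.0548). Without the *pstS* *phoU* 16 h array 17 did not, among them CCNA_00619, CCNA_00620 and CCNA_00425.

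The direct test compared the depletion ratios between the strains (3 arrays against 7, with time in the model). It asked whether the *pstS* insertion alters the response to vanillate withdrawal. Cy3, compared below, was already higher in that strain for the Pho signalling (median 2.08) and general secretion (2.40) lists. For these a lower ratio cannot tell a lost response from one already present with vanillate. Values are the *pstS* *phoU* strain minus the *phoU* strain. *phoU* had a difference of -1.35 ± 0.29 (SE, adjusted p = 0.154), *phoB* of -1.03 ± 0.26 (SE, adjusted p = 0.177), *pstC* of -1.11 ± 0.31 (SE, adjusted p = 0.184), *pstA* of -0.88 ± 0.23 (SE, adjusted p = 0.177) and *pstB* of -0.93 ± 0.28 (SE, adjusted p = 0.19), and none of them passed. The difference was 0.35 for *phoR* and -0.049 for *pstS*. The genes of smallest p were CCNA_01369, an acyl-CoA dehydrogenase gene (0.79 ± 0.089 SE, adjusted p = 0.0953), the hypothetical CCNA_01304 (-0.96 ± 0.13 SE, adjusted p = 0.119), the ribosomal protein genes *rpsC* (-0.65 ± 0.088 SE, adjusted p = 0.119) and *rplN* (-0.65 ± 0.092 SE, adjusted p = 0.119), and the protease gene CCNA_01522 (0.79 ± 0.13 SE, adjusted p = 0.124). Between arrays of the same slide and time the difference of *pstC* was -0.025 and that of *phoB* -0.16 on slide 1 (2 h), and -1.74 and -1.5 on slide 2 (mean of 7 and 16 h). The model fits 1 strain difference for all times, so a difference that changes with time adds to its error. By camera 3 fixed lists lay lower in the *pstS* *phoU* strain, with no member passing. The Pho signalling list had a median of -0.93 (adjusted p = 0.0169, 0 up and 5 down over the list alone). The ribosomal median was -0.17 (adjusted p = 0.00163, 2 up and 14 down). For transposases it was -0.27 (adjusted p = 0.0005, 0 up and 0 down). The flagellum list lay higher at 0.12, with none passing (adjusted p = 0.0112, 0 up and 0 down). With an estimated correlation adjusted p was 0.763 for each of these lists. Of the lists chosen later, general secretion lay lower, with a median of -0.93, where none passed (0 up and 0 down over the list alone, and for the list shift adjusted p = 1.63e-05, and 0.327 with an estimated correlation), and sulfate higher, with one of 0.34, where none passed (2 up and 0 down over the list alone, and for the list shift adjusted p = 0.00764, and 0.252 with an estimated correlation). Scale normalization moved the medians to -0.61 for the Pho signalling list, 0.044 for flagellum, -0.18 for transposases and -0.43 for general secretion, and median centring to -0.38 for the ribosomal list (-0.082 with the processed signals) and -0.49 for transposases. limma called 0 genes, with 831 at an unadjusted p below 0.05. The count was 1 with median centring, 30 with scale normalization and 2072 (993 up and 1079 down) with 1 mean per strain and time, its error again from *phoU* replicates alone, where *phoU* (-1.34, adjusted p = 0.00284), *phoB* (-1.11, adjusted p = 0.00016), *pstC* (-1.19, adjusted p = 9.77e-05), *pstA* (-0.93, adjusted p = 0.000287), *pstB* (-0.99, adjusted p = 0.00011) and *phoR* (0.41, adjusted p = 0.00145) passed. It was 46 (31 up and 15 down) without the *phoU* 16 h or the *pstS* *phoU* 16 h array, when CCNA_01369, CCNA_01304, *rpsC*, *rplN* and CCNA_01522 passed with adjusted p between 0.0124 and 0.0352. It was 3 without the *pstS* *phoU* 7 h array and 1 without the *pstS* *phoU* 2 h array, which was *pstB*.

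**Figure D2:**
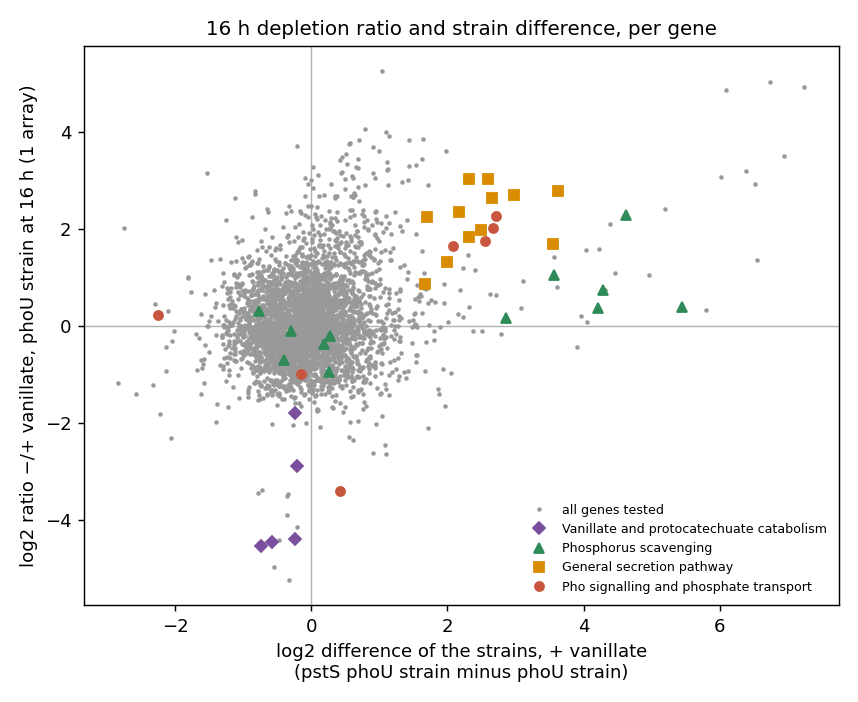
Log2 ratio on the *phoU* 16 h array (vertical axis, 1 array) against the log2 difference in Cy3 signal between the strains (horizontal axis, *pstS* *phoU* strain minus *phoU* strain), 1 grey point per gene, with coloured symbols for the members of 4 gene lists, of which general secretion was chosen after the values were seen. *pstC* lies at 2.71 between the strains and 2.26 at 16 h, and *vanA* at -0.23 and -4.39.

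The strains were last compared in Cy3 alone, from cells kept with vanillate for the same hours, to ask how the strains differ without depletion (3 arrays against 7, with time in the model). Every array of the *pstS* *phoU* strain had a lower median Cy3 signal (806 to 2623.5) than every array of the *phoU* strain (4479 to 10951.5), so the signal level was confounded with the strain. *pstS* was lower in the strain with the insertion, with a difference of -2.25 ± 0.14 (SE, adjusted p = 5.68e-06), or -1.99 between arrays of the same time on slide 1 (2 h) and -2.37 on slide 2 (mean of 7 and 16 h). The labels do not place the insertion within *pstS*, so this is not necessarily the level of the whole transcript. The phosphate genes beside *phoU* were higher: *pstC* by 2.71 ± 0.16 (SE, adjusted p = 3.34e-06), *phoB* by 2.67 ± 0.18 (SE, adjusted p = 7.86e-06), *pstB* by 2.55 ± 0.15 (SE, adjusted p = 2.35e-06) and *pstA* by 2.08 ± 0.27 (SE, adjusted p = 0.000491), and at the same times on slides 1 and 2 *pstC* by 2.17 and 2.95 and *phoB* by 2.12 and 3.02. *ppk1* was higher by 0.77 ± 0.17 (SE, adjusted p = 0.00687), while *phoU* (0.42 ± 0.52 SE, adjusted p = 0.543), *phoR* (-0.15 ± 0.17 SE, adjusted p = 0.501), *vanA* (-0.23 ± 0.39 SE, adjusted p = 0.658) and *vanR* (-0.24 ± 0.19 SE, adjusted p = 0.331) did not pass. In the Pho signalling list 4 were higher and 1 lower (4 up and 1 down over the list alone). The median over the list was 2.08 (adjusted p = 0.0326, and 0.385 with an estimated correlation). TonB-dependent receptor genes had the largest differences in both directions. CCNA_00759 was higher by 7.24 ± 0.13 (SE, adjusted p = 1.49e-09), with 6.92 and 7.43 at the same times on the slides, followed by CCNA_00486 (6.94), CCNA_01047 (6.73), CCNA_00598 (6.55), CCNA_03019 (6.52), CCNA_00170 (6.39) and CCNA_02232 (6.02), the surface protein gene CCNA_00776 (5.79) and the hypothetical CCNA_00169 (6.08), while CCNA_02048 (-2.83), *chvT* (-2.57), CCNA_01155 (-2.22) and CCNA_01738 (-2.14) were lower. Of the 55 receptors 13 were higher and 23 lower (13 up and 25 down over the list alone), and their mean was 0.49 but their median -0.14, or 0.10 with median scaling (adjusted p = 0.83, and 0.937 with an estimated correlation). Genes for the release of phosphate from organic compounds were higher: the phosphodiesterase genes CCNA_03276 (5.44) and CCNA_03381 (4.62), the phospholipase C gene CCNA_03126 (4.29), the alkaline phosphatase gene CCNA_00487 (4.21) and the phytase gene CCNA_01353 (3.57). Of the 12 scavenging genes 6 were higher and 2 lower (6 up and 2 down over the list alone). These genes had a median of 1.57 (adjusted p = 0.000392, and 0.17 with an estimated correlation). In the polyphosphate and alarmone list 1 was higher and 4 lower (1 up and 4 down over the list alone), with *ppx1*, for exopolyphosphatase, at -1.61, and the list did not shift (adjusted p = 0.465, and 0.679 with an estimated correlation).

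Ribosomal protein and tRNA synthetase genes were lower in the strain with the insertion. Of 55 ribosomal protein genes, 1 was higher and 31 lower (1 up and 34 down over the list alone). The list median was -0.52 (adjusted p = 4.29e-05, and 0.45 with an estimated correlation), with *rplV* (-1.30) and *rpsE* (-1.27). Of 21 tRNA synthetase genes none were higher and 16 lower (0 up and 19 down over the list alone). The median of the list was -0.61 (adjusted p = 4.29e-05, and 0.385 with an estimated correlation), with *trpS* at -0.80. Of 17 division genes none were higher and 9 lower (0 up and 10 down over the list alone), with *ftsB* (-1.53) and *ftsA* (-0.87). Of 91 flagellum and chemotaxis genes 6 were higher and 27 lower (5 up and 27 down), with *flgB* (-1.47) and *fliG* (-1.09). Of 37 respiratory genes 1 was higher and 16 lower (1 up and 18 down), with *nuoK* at -0.76. Their medians were -0.47, -0.24 and -0.33 (adjusted p = 0.0123, 0.0326 and 0.0189, and 0.385, 0.669 and 0.385 with an estimated correlation). The transposase list lay higher, and 10 were higher and 3 lower (10 up and 3 down over the list alone). The list had a median of 0.17 (adjusted p = 0.0326, and 0.363 with an estimated correlation). The general secretion list, chosen later, lay higher too, and 12 were higher and none lower (12 up and 0 down over the list alone). Here the list median was 2.40 (adjusted p = 1.22e-13, and 0.0459 with an estimated correlation), with *pulD* (3.62) and *pulE* (2.98). The other genes far lower in this strain were CCNA_03638 (-2.76), CCNA_02741 (-2.33) and CCNA_02774 (-2.30), all hypothetical, *ccbF* (-2.14) and CCNA_03766, annotated as the ribosome maturation gene rimM (-2.10). The cell cycle regulators *pleC* (-1.15) and *dnaA* (-0.99) were lower and the stalk gene *bacA* (1.09) higher, while neither list shifted (0.175 and 0.0702 as adjusted p). The lists of vanillate catabolism, heat shock, general stress, oxidative stress, SOS, pili and holdfast, iron, central carbon metabolism and efflux did not shift (adjusted p between 0.112 and 0.981). In the first, *vanB* had a difference of -0.75 ± 0.25 (SE, adjusted p = 0.0396).

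limma called 1637 of 3823 genes, 663 higher and 974 lower in the *pstS* *phoU* strain. Of these 1210 had every array of one strain above every array of the other, and 368 differed by at least 1, 207 higher and 161 lower. With median scaling in place of quantile normalization the median difference of all genes moved from -0.071 to 0.10, and 934 of the 1660 genes that then passed were higher and 726 lower. The ribosomal list then had a median of -0.18 and the tRNA synthetase list of -0.63. The respiratory list moved to -0.20 and the transposase list to 0.46. With the scanner software's processed signals these were -0.24 for the ribosomal, -0.20 for the respiratory and 0.27 for the transposase list. A slide block gave 2028 genes and a scan session block 1280. Without the *pstS* *phoU* 7 h array 1079 passed and 15 of the 90 named genes that passed no longer did, among them *ppk1* (0.58, adjusted p = 0.0575), and *vanB* (adjusted p = 0.116 without that array) also did not pass without *phoU* 2 h replicate 1, *phoU* 7 h replicate 1, the *pstS* *phoU* 2 h array or either 16 h array (adjusted p between 0.0726 and 0.13).

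**Figure D3:**
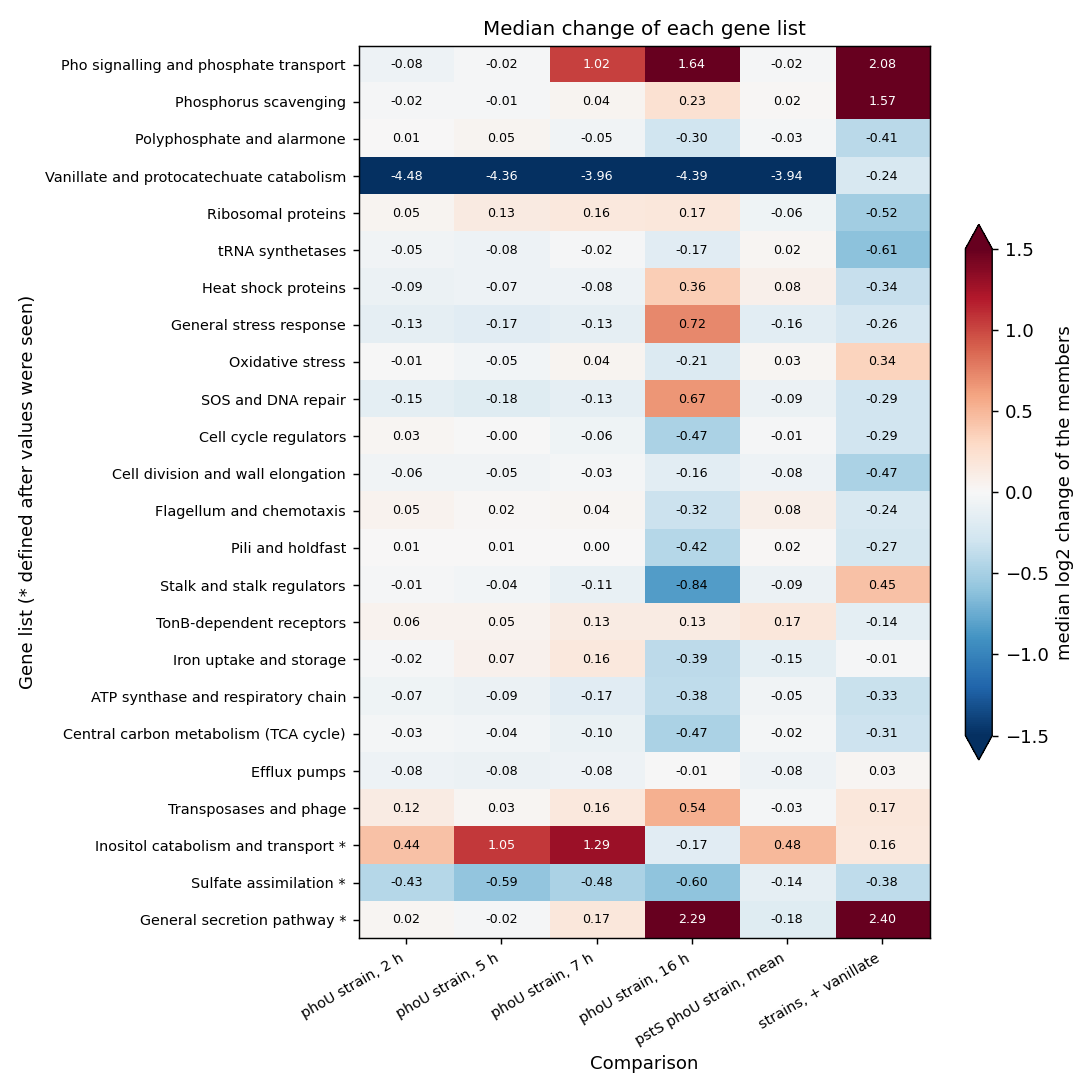
Median log2 change of the members of each gene list (vertical axis) in 6 comparisons (horizontal axis), as colour and printed value, with an asterisk on lists chosen after the values were seen. The vanillate list lies at -4.48, -4.36 and -3.96 at 2, 5 and 7 h, and the respiratory list, at -0.17 at 7 h, turns to 0.017 with median centring.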

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

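The tests of slide, construct and wider response and the splits for the ratios were chosen after the results were seen, and the splits in Cy3 were laid down before. How the spread of a value entered the reading of the wider response was settled after that value was seen.

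Between 2 h and 7 h in the *phoU* strain 6 genes passed the test of the difference itself, with rises of 1.40 for *pstC*, 1.40 for *pstB*, 1.14 for *phoB*, 1.1 for *pstA*, 0.84 for CCNA_00206 and 0.71 for CCNA_00207. The lower of the 2 within-slide median rises of the 4 phosphate genes was 1.205. Choosing genes with every 7 h array above every 2 h array nearly fixes this, so it is no test of slide or scan session. The slide 2 arrays of both times were read in the same scan session. The labels do not say where the vanillate-driven copy of *phoU* lies. The median ratio of the 4 genes was -0.077 at 2 h, when *phoU* had already fallen by 4.06. They had not risen by then, but choosing on 7 h minus 2 h favours low 2 h values. An effect of the construct from the stop of *phoU* transcription is therefore left undecided. A slower effect of the construct was not tested. A wider Pho response may be part of the rise, and this cannot be decided here: the other 51 genes that are higher in Cy3 of the *pstS* *phoU* strain by a log2 of at least 2 had a median rise of 0.086 (bootstrap SE 0.036) against a bound of 0.1. By the bound alone this would have argued against that explanation, but the median lay within 1 bootstrap SE of it. It was above the range that held 95% of the medians of 10000 random lists (-0.045 to 0.021) and far below that of the 4 genes. Loss of PhoU over time, which the design names, remains an open explanation. No test set it apart from the time spent without vanillate.

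Opposite signs on every array of the strains were seen for *rpsC*, with a mean of 0.45 in the *phoU* strain, and for CCNA_01021, with -0.97. In the strain comparison neither passed (adjusted p = 0.119 and 0.124). Both passed with scale normalization (0.0466 and 0.0386) and with 1 mean per strain and time (0.000401 and 0.000403), *rpsC* without either 16 h array (0.0223) and CCNA_01021 without the *pstS* *phoU* 7 h array (0.0362). Of the 36 array targets without a gene name, which the comparisons leave out, 7 passed in the *phoU* strain at 7 h, 24 at 16 h, 10 in the *pstS* *phoU* mean and 19 between the strains in Cy3, each adjusted over these targets. The count at 16 h rests on an SE that is too small for that array. Of these targets 27 have coordinates, and 27 of those overlap a gene of the reference annotation.

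For the comparison of the strains, splits of the 10 arrays into 3 and 7 were drawn (100, of which 98 could be fitted). In Cy3, of 98 splits only the real one gave 1637 genes, the highest other giving 1, so a random split of arrays is argued against. Chance between cultures and the strain difference in signal level, which goes the same way, are not. For the strain difference of the ratios, 98 of 98 splits gave as many as the real 0 (limma, adjusted p below 0.05). With a real count of 0 every split does so by construction, so they say nothing about chance. The highest other split, both 5 h arrays and the 16 h array of the *phoU* strain against the rest, gave 2046, which points to a structure of the samples, the 16 h array standing apart.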

How the results depend on the processing

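The fit without the 16 h arrays of both strains, the raised error at 16 h and the error from the spread of the 3 *pstS* *phoU* arrays were chosen after the results were seen. The cause of each difference was not tested, except that the minimum log2 change of 1 passes fewer genes by construction and that leaving out arrays leaves fewer samples. The counts of genes passing in the *phoU* strain at 2, 5, 7 and 16 h were 39, 89, 187 and 2831. A minimum log2 change of 1 left 20, 30, 32 and 816, with 23 of 724 for the mean of the *pstS* *phoU* strain and 368 of 1637 for the Cy3 comparison. Median centring gave 67 at 7 h, 0 in place of 6 between 2 h and 7 h (limma, adjusted p below 0.05), 72 for the *pstS* *phoU* mean and 1 in place of 0 for the strain difference of the ratios. Scale normalization gave 76, 173 at 16 h, 2, 454 and 30 for the same results. With the error at 16 h raised by the extra probe noise of the array 1494 genes passed, and 12 of 103 named genes that passed were lost. With the error of the *pstS* *phoU* mean taken from the spread of its own 3 arrays 31 passed, and 50 of 66 were lost. A replicate block gave 3 between 2 h and 7 h and 254 for the *pstS* *phoU* mean, although the replicate numbers do not pair the ratios (correlation across genes of replicate differences -0.252 to 0.289), and a slide block gave 3 between 2 h and 7 h. For the strain difference of the ratios, a model with 1 mean per strain and time gave 2072, and the fit without the 16 h arrays 46. With 1 array left out at a time the counts ranged from 22 to 41 at 2 h, 24 to 95 at 5 h, 46 to 187 at 7 h, 2753 to 2842 at 16 h, 2 to 14 between 2 h and 7 h, 109 to 797 for the *pstS* *phoU* mean, 0 to 46 for the strain difference of the ratios and 1079 to 1633 in Cy3. Of 59 shifts of the 21 fixed lists, 0 passed with an estimated correlation. Of 17 shifts of the 3 lists chosen later, 1 did, that of general secretion in Cy3. The other alternatives kept these counts within 1.5 times. Of 689 ratio results for named genes, median centring left 610 on their side of the threshold, with 74 lost, 4 gained and 1 turned round: *coxB* at 7 h, from -0.28 to 0.091. Scale normalization lost 115 of them. Over all fits without 1 array 7388 results kept their side, 356 were lost and 62 gained. Signal over background set no limit on the named genes, since 0 of 307 lacked a spot well above background on any array, and the number of arrays limits the precision.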

Other observations

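The tests of scan session on the CCNA_01854 neighbourhood, of scan session, label and noise share on the 16 h array, and of the 51-gene set were chosen after the results were seen, while those of probe noise were laid down before, apart from how the SE of the probe correlation was used.

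A set of 51 genes outside the Pho signalling list, defined after the values were seen as higher by a log2 of at least 2 in Cy3 of the *pstS* *phoU* strain than on the 5 h arrays of the *phoU* strain, was followed over depletion time in the *phoU* strain. The median of the set was 0.058 at 2 h (percentile 75.3 of 10000 random lists), 0.17 at 7 h (percentile 100), when 9 members rose, and 1.20 at 16 h, when 47 lay above 0.

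The *phoU* 16 h array had an SD of log2 ratios of 0.937 against 0.296 to 0.362 on the others. The scan session or slide is argued against, since the other arrays of its scan session, on the same slide, had SDs of at most 0.311, and so is a wrong strain or channel label, since *phoU* stood at -3.41 and *pstS* had the Cy3 signal of the *phoU* strain, though the time on the label was not tested. Spot noise alone was left undecided by the correlation across genes of odd and even probes, which was 0.902 (bootstrap SE 0.00465) against a bound of 0.9, above which noise would have been argued against had its SE not been taken into account, a rule added after the value was seen. Noise as most of the spread is argued against, since the noise SD of a gene mean was 0.212. A wider Pho response is a candidate explanation of part of the spread: the 51 genes had a median of 1.2, above the range that held 95% of the random lists (-0.019 to 0.47), and 30 of them rose by over 1. A difference in growth state after 16 h, which these arrays cannot test, remains open.

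The adjoining genes CCNA_01854 to CCNA_01860 (chromosome 1, 1985974 to 1995030) swung together between arrays of the same strain, and were noticed in the values. Their median log2 ratio was 0.05 and -0.033 on the 2 h arrays of the *phoU* strain, -1.49 and -1.13 at 5 h, 1.47 and -0.13 at 7 h and -2.30 at 16 h, and 0.21, -2.51 and -0.027 on the *pstS* *phoU* arrays at 2, 7 and 16 h. A scan session effect is argued against, since the 7 h and 5 h arrays of scan session 2 differed by a median of 3.04, and so is spot noise, since odd and even probes of these genes correlated at 0.987 over genes and arrays. No biological explanation was tested.

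Among the targets without a gene name on the array, the one at chromosome 1, 3578931 to 3579269, had a log2 ratio of 6.02 at 16 h. It overlaps CCNA_03906, a protein-coding gene of the reference annotation.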
